A study of Homo sapiens with 4 samples.

How the data were processed

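Total RNA of MOLM-14 cells was measured on 4 arrays, 2 from cells treated with GSK621 and 2 from cells treated with rapamycin and then GSK621. Per the labels' protocols, RNA was isolated on silica columns in an automated system, and biotin-labelled sense-strand target was made from total RNA for Affymetrix whole-transcript arrays. Per the submitters' processing notes, R 2.15.3 and Partek were used, and the role of each was not given. The background correction, the normalization between arrays, the summary of probes into probe sets and the log base were not given in the sources used here. The values deposited by the authors were read as log2 expression, 1 value per gene-level probe set and array. They ran from 1.84 to 13.28 with near-equal quantiles on the 4 arrays, as normalized probe set summaries do. A natural log would have put the highest signal at 585694, above the 65535 that a 16-bit scanner can record, which leaves log2 as the usual scale of such summaries. No detection calls and no signal over background were used, so whether a dim probe set stood above background is unknown.

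Groups and replicate numbers were taken from the sample titles. Each row of the table was named through the annotation of the array platform, which gave 1 symbol to 24244 of the 25582 probe sets, several symbols to 0 and none to 1338. Gene types and older symbols were looked up in the NCBI RefSeq gene table of GRCh38.p14, used for names and types and not for coordinates. Of the 24241 genes tested, 17723 were protein-coding, 3902 were long non-coding RNA genes, 1086 were microRNA genes and 48 had no RefSeq type. For 3 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used. In matching list symbols, 6 renamed genes with ambiguous older names were assigned by hand after the files had been looked at.

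The values were used as deposited, with no filter, no further normalization and no pseudocount. Rapamycin then GSK621 minus GSK621 was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. The fit had 2 residual degrees of freedom and 3.39 prior degrees of freedom. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so such a test was not used for single genes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 36 lists. Camera with a correlation estimated per list was run beside it, and its p then rests on the 2 residual degrees of freedom. So was fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. A list median was also set against 10000 random lists matched on mean level in 50 bins.

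The design, the lists, the rule for named genes and the other settings were fixed before the data were examined. Under that rule the text names 12 genes per direction with the largest difference among those past the threshold with non-overlapping arrays. Where fewer passed, as here, the places are filled in order of unadjusted p among genes with non-overlapping arrays and given as values. It also names up to 4 members with the smallest p in each list and 16 pathway genes whatever their values, of which 1 is not reported here. VEGFA, ATF2, IFI27 and the metallothioneins other than MT1G fall outside the rule and were named after their values were seen.

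The other settings fixed in advance were the replicate number as a block, quantile normalization, centring of arrays, a filter on dim genes, a variance trend with robust estimation, no variance moderation, the mean of the probe sets of a gene, every probe set, other thresholds, leaving out each array in turn, and the other list tests. Removal of a level-dependent trend, protein-coding genes alone and genes in 1 list alone were added after seeing the data. The method was tested on simulated data with the means and spread of these arrays over 24241 genes. It recovered 66% of 100 genes changed by 1 on the log2 scale and 98% of 100 genes changed by 2, with 18 calls among unchanged genes. Camera at the preset correlation called 12 of 12 lists shifted by 0.3 and 0 of 14 unshifted lists. The genes were simulated as independent of each other, which real members of a pathway are not.

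Pearson correlations between arrays over all probe sets, which are not independent replicates, were 0.994 within each group and 0.993 to 0.994 between groups. The median absolute difference between arrays was 0.126 and 0.120 within the groups and 0.137 to 0.143 between them. The samples are labelled as biological replicates, and no culture date, array batch or scan date was used here.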

Results

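Gene expression was measured on 4 Affymetrix whole-transcript arrays of MOLM-14, an established human acute myeloid leukaemia cell line. In 2 cultures the cells received GSK621, an activator of the energy sensor kinase AMPK, at 30 µM for 6 h. In the other 2 cultures rapamycin, an inhibitor of the growth-controlling kinase complex mTORC1, was given at 10 nM for 12 h before the same GSK621 treatment. The labels describe the cultures as biological replicates, so n = 2 per group. The design compares the transcriptomes of cells given GSK621 with and without rapamycin beforehand, and the activity of AMPK and mTORC1 was not measured here. Cells without GSK621 and cells with rapamycin alone were not analysed here. Each difference is thus between rapamycin followed by GSK621 and GSK621 alone, and the effect of GSK621 itself was not measured. An effect of rapamycin itself cannot be told apart from a changed response to GSK621. The table held 25582 probe sets, of which 24244 carried a gene symbol and 1338 were unnamed. After reduction to 1 probe set per symbol, 24241 genes were tested. Array medians lay between 5.37 and 5.43 on the log2 scale. The number of arrays limits the precision, with a median standard error (SE) of a log2 difference of 0.11.

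Rapamycin before GSK621 went with lower expression of HIF1 targets, ATF4 stress response genes, endoplasmic reticulum chaperones, sterol and fatty acid synthesis genes, glycolysis genes and mitosis genes, each tested as a list at a preset correlation. None of these calls held when the correlation was estimated (adjusted p = 0.367 with an estimated correlation for ATF4 genes and chaperones, 0.519 for the others). In simulated data that test recovered 0 of 12 shifted lists, so a call lost with it does not decide whether a list changed. Of these lists, that of ATF4 genes alone also passed with fry (adjusted p = 0.0479). Ribosomal proteins, ribosome assembly factors, nucleotide synthesis genes and G1/S genes rose as lists by smaller amounts at the preset correlation. These calls were lost too (adjusted p = 0.622 with an estimated correlation for ribosome assembly, 0.519 for the others), and those of ribosome assembly and G1/S genes also when 1 array was left out. PIM1, a serine/threonine kinase that favours survival of blood cells, had a mean level of 9.54 ± 0.03 (SD, n = 2) after rapamycin and GSK621 against 8.16 ± 0.01 after GSK621 alone, a 2.60-fold difference. At the other end, the splicing regulator ESRP1 had a mean of 7.16 ± 0.01 against 8.52 ± 0.09, a 2.56-fold difference. No single gene passed the threshold over all genes, so individual genes are given as values, except where a member passed when adjusted over its list alone.

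With limma, 0 of the 24241 genes reached an adjusted p under 0.05, and the smallest adjusted p was 0.172. At an unadjusted p under 0.05 there were 2064 genes, 1045 higher and 1019 lower after rapamycin, where 1212 would be expected by chance. The arrays split by replicate number gave 1257 such genes, and the remaining split gave 756. The count without a treatment contrast thus varied in these arrays. The arrays of the groups did not overlap for 4966 genes with higher and 4593 genes with lower values after rapamycin, which is 39.4% of genes against 33.3% by chance. Moderation with a variance trend and robust estimation called 74 genes, 20 higher and 54 lower. These included 23 of the 24 genes named as highest and lowest here. The 24 were picked for small p in the same arrays, so this overlap is no independent support. In that setting the split by replicate number gave 0 genes and the remaining split gave 0. The treatment difference adds to the residual spread of both splits, so they are not a clean baseline. A fit without moderation called 1 gene, ATF2, at a log2 difference of −0.19 with an SE of 1.74e-04. With genes above the median level alone, 3 genes passed, PIM1 and ALDH1A3 higher and ESRP1 lower.

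The 12 genes with the smallest p among those with higher values included ALDH1A3, a retinaldehyde dehydrogenase, with a log2 difference of 1.45 ± 0.10 (SE). The pattern recognition receptor TLR2 had 1.11 ± 0.10, and OCSTAMP, a membrane protein of osteoclast fusion, had 1.16 ± 0.11. The arrestin family member ARRDC4 had 1.29 ± 0.16, the microRNA gene MIR221 had 1.04 ± 0.11, and PRAM1, an adaptor protein of myeloid cells, had 0.95 ± 0.10. The transcribed pseudogene ANKRD18DP had 0.99 ± 0.13 and the zinc finger gene ZNF33B had 0.73 ± 0.10. LINC01255 (1.16 ± 0.14), DUX4 (0.91 ± 0.10) and MIR2276 (0.83 ± 0.11) lay between percentiles 13 and 17.2 of mean level, and DUX4 belongs to a family of near-identical copies, so its signal is uncertain.

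Among the 12 genes with lower values and the smallest p, SDC3, a cell surface proteoglycan, had a log2 difference of −1.37 ± 0.14. The secreted stress marker GDF15 had −1.07 ± 0.10, and the glycoprotein hormone STC1 −1.09 ± 0.09. The lipocalin APOD had a mean of 3.90 ± 0.02 (SD, n = 2) against 4.90 ± 0.04. The metal-binding protein gene MT1G had −1.03 ± 0.10 and WIPI1, a phosphoinositide-binding protein of autophagosome formation, had −0.85 ± 0.09. The netrin receptor UNC5B had −1.01 ± 0.10, the small GTPase GEM −1.04 ± 0.11 and the transcriptional repressor PRDM1 −0.96 ± 0.11. VWA5A had −1.12 ± 0.11, and CAP2, an actin-binding protein, had −1.18 ± 0.13. The smallest adjusted p among the 24 genes was 0.172, for PIM1, ALDH1A3 and ESRP1.

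**Figure D1:**
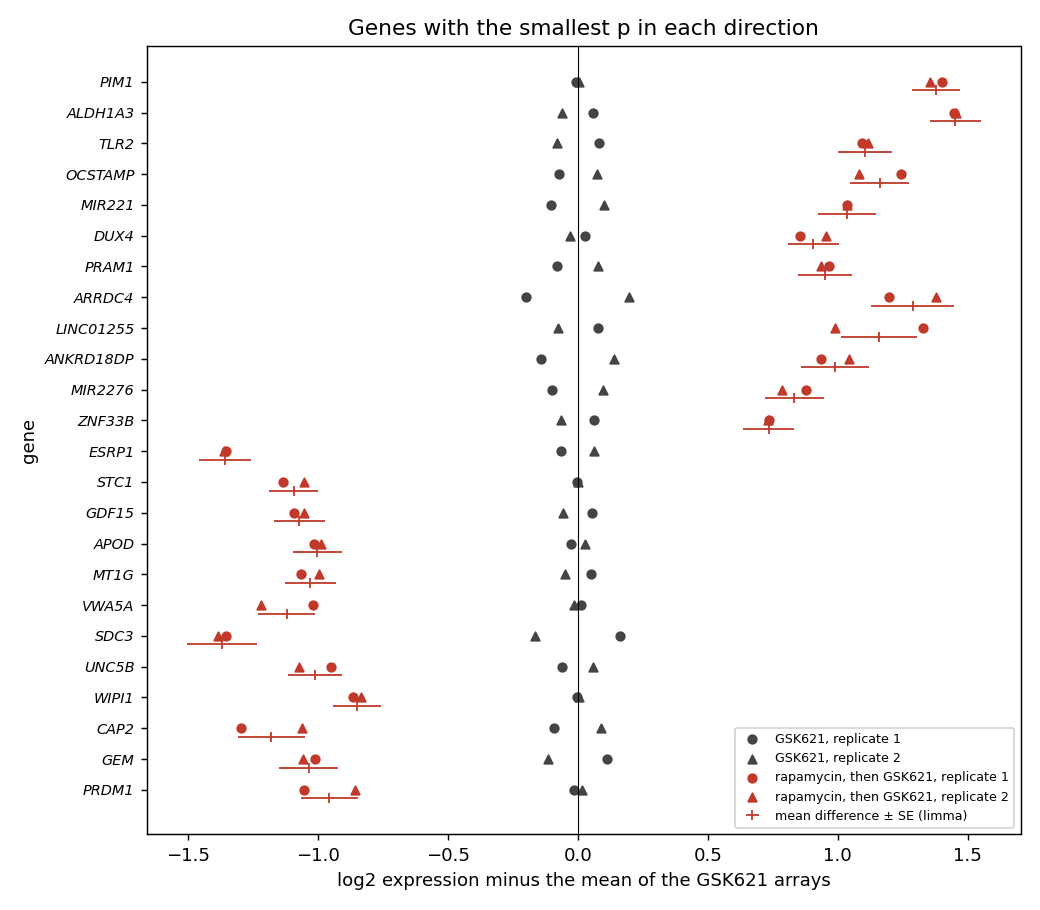
Log2 expression of the 24 named genes on each of the 4 arrays, minus the mean of the GSK621 arrays, with a circle for replicate 1 and a triangle for replicate 2 in grey (GSK621) and red (rapamycin then GSK621), and a bar for the mean difference ± SE from limma. Both red points lie on the same side of both grey points for each gene, as the rule for naming genes required. PIM1 shows a difference of 1.38 and ESRP1 of −1.36.

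Genes of the treated pathways were read whatever their values. ATF4, the transcription factor of the integrated stress response, had a log2 difference of −0.00 ± 0.11, with overlapping arrays and a sign that turned with quantile normalization, with centring, without GSK621 replicate 2 and without replicate 1 of rapamycin then GSK621. Of its target genes, DDIT3 had −0.50 ± 0.15, TRIB3 −0.53 ± 0.12, SESN2 −0.42 ± 0.13, ASNS −0.12 ± 0.10 and CHAC1 −0.07 ± 0.11. DDIT4, an inhibitor of mTORC1 signalling, had −0.53 ± 0.10. The AMPK catalytic subunit gene PRKAA1 had −0.12 ± 0.09 and MTOR had 0.25 ± 0.11. The transcription factor MYC had 0.28 ± 0.09, cyclin CCND3 0.37 ± 0.10 and the insulin receptor substrate IRS2 0.10 ± 0.11. Some of these values moved by over 1.5 times when an array was left out. SESN2 came to −0.27 without GSK621 replicate 2, where CHAC1 turned to 0.0199. Without replicate 1 of rapamycin then GSK621, MTOR came to 0.15 and IRS2 to 0.0201, the lowest of a range up to 0.18. CHAC1 came to −0.15 without GSK621 replicate 1.

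Of 36 gene lists fixed before the data were examined, 13 passed an adjusted p under 0.05 with camera at a preset inter-gene correlation of 0.01, 9 lower and 4 higher after rapamycin. The lists held 966 entries, of which 875 were measured, and 31 genes stood in more than 1 list. Over all genes, 0 members of any list passed, and counts of members below are adjusted over the list alone. That adjustment does not correct for the number of lists, so members said to rise or fall by it are candidates. With an estimated correlation 0 lists passed, and with fry 1 list did, that of ATF4 stress genes (adjusted p = 0.0479).

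HIF1 targets, genes of the response to low oxygen, fell as a list, with 20 of 21 measured members lower and a median log2 difference of −0.37 (camera adjusted p = 4.07e-14, adjusted p = 0.519 with an estimated correlation). Of these, 14 fell when adjusted over the list alone, among them HILPDA (−0.53 ± 0.10), ADM (−0.79 ± 0.15), DDIT4 and BNIP3 (−0.56 ± 0.13). The ATF4 stress response list fell with 26 of 29 members lower and a median of −0.27 (camera adjusted p = 1.65e-09, adjusted p = 0.367 with an estimated correlation). In it 7 members fell when adjusted over the list alone, namely GDF15, ATF5 (−0.61 ± 0.10), ATF3 (−0.75 ± 0.14), DDIT4, TRIB3, VEGFA (−0.43 ± 0.10) and CTH (−0.41 ± 0.10). DDIT4 and VEGFA stood in both lists. Endoplasmic reticulum chaperones and targets of XBP1 and ATF6 fell with 21 of 25 members lower and a median of −0.20 (camera adjusted p = 5.44e-09, adjusted p = 0.367 with an estimated correlation). Adjusted over the list alone, 11 of them fell, including the stress sensor kinase ERN1 (−0.77 ± 0.11), the chaperones HYOU1 (−0.52 ± 0.10) and HSPA5 (−0.48 ± 0.10), and EDEM1 (−0.47 ± 0.10).

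Sterol synthesis and uptake genes fell as a list, with 18 of 19 measured members lower and a median log2 difference of −0.28 (camera adjusted p = 3.23e-09, adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone 0 members passed, with the smallest adjusted p at 0.0505. STARD4 had −0.54 ± 0.10, HMGCS1 −0.62 ± 0.17, INSIG1 −0.37 ± 0.11 and MSMO1 −0.36 ± 0.10. Fatty acid synthesis genes fell with 10 of 13 members lower and a median of −0.28 (camera adjusted p = 6.20e-05, adjusted p = 0.519 with an estimated correlation). The NADPH-producing malic enzyme ME1 (−1.41 ± 0.17), the desaturases FADS2 (−0.76 ± 0.10) and FADS1 (−0.49 ± 0.09) and the acetyl-CoA synthetase ACSS2 (−0.52 ± 0.09) were the 4 that fell when adjusted over the list alone. Glycolysis genes fell with 17 of 22 members lower and a median of −0.15 (camera adjusted p = 5.00e-05, adjusted p = 0.519 with an estimated correlation). The 6 that fell when adjusted over the list alone included the glucose transporter SLC2A1 (−0.76 ± 0.11), hexokinase HK2 (−0.67 ± 0.13), ALDOC (−0.51 ± 0.10) and ENO2 (−0.62 ± 0.13). Serine, glycine, one-carbon, proline and asparagine synthesis enzymes fell with 12 of 16 members lower and a median of −0.08 (camera adjusted p = 0.00412, adjusted p = 0.631 with an estimated correlation). That call was lost without GSK621 replicate 2 (adjusted p = 0.0718) and without replicate 2 of rapamycin then GSK621 (0.110), over a range of 1.58e-04 to 0.631 in all settings. GOT1 had −0.48 ± 0.10, ALDH1L2 −0.35 ± 0.09 and PHGDH −0.24 ± 0.10, and 0 members passed when adjusted over the list alone.

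Cell cycle lists moved in both directions. G2/M and mitosis genes fell with 31 of 36 members lower and a median log2 difference of −0.19 (camera adjusted p = 3.39e-08, adjusted p = 0.519 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, had −0.60 ± 0.11, and NUF2 (−0.39 ± 0.10), BUB1 (−0.35 ± 0.11) and NEK2 (−0.32 ± 0.10) followed, with 0 members past the threshold when adjusted over the list alone. CDK inhibitors and p53 targets fell with 19 of 24 members lower and a median of −0.15 (camera adjusted p = 5.76e-05, adjusted p = 0.519 with an estimated correlation). GADD45A (−0.82 ± 0.10) and CDKN1A (−0.53 ± 0.11) were the 2 that fell when adjusted over the list alone, and TP53INP1 had −0.43 ± 0.12 and SESN1 −0.47 ± 0.14. G1/S and DNA replication genes rose with 28 of 41 members higher and a median of 0.11 (camera adjusted p = 8.59e-04, adjusted p = 0.519 with an estimated correlation). The cyclins CCNE1 (0.49 ± 0.10) and CCNE2 (0.49 ± 0.12) and the uracil glycosylase UNG (0.47 ± 0.10) were among the highest of them, and 0 members passed when adjusted over the list alone. The G1/S call was lost without replicate 1 of rapamycin then GSK621 (adjusted p = 0.0507, range over all settings 2.88e-04 to 0.519).

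Ribosomal protein genes rose as a list, with 33 of 39 measured members higher and a median log2 difference of 0.12 (camera adjusted p = 4.01e-05, adjusted p = 0.519 with an estimated correlation). RPL31 had 0.54 ± 0.10, RPL19 0.34 ± 0.09, RPS24 0.30 ± 0.10 and RPS15A 0.29 ± 0.10. The list named 59 genes, and 20 were not measured under a name. Ribosome assembly and rRNA processing factors rose with 27 of 32 members higher and a median of 0.12 (camera adjusted p = 2.14e-04, adjusted p = 0.622 with an estimated correlation), a call that was lost without GSK621 replicate 1 (adjusted p = 0.0761, range over all settings 6.32e-06 to 0.622). RRP12 had 0.30 ± 0.09, NOP56 0.30 ± 0.10, RRS1 0.54 ± 0.19 (0.27 without GSK621 replicate 1) and NOP14 0.24 ± 0.09. Purine and pyrimidine synthesis genes rose with 14 of 18 members higher and a median of 0.12 (camera adjusted p = 0.00273, adjusted p = 0.519 with an estimated correlation). The CTP synthase CTPS1 had 0.43 ± 0.10, DHODH 0.27 ± 0.10, PFAS 0.26 ± 0.09 and ATIC 0.26 ± 0.10. In these 3 lists 0 members passed when adjusted over the list alone.

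**Figure D2:**
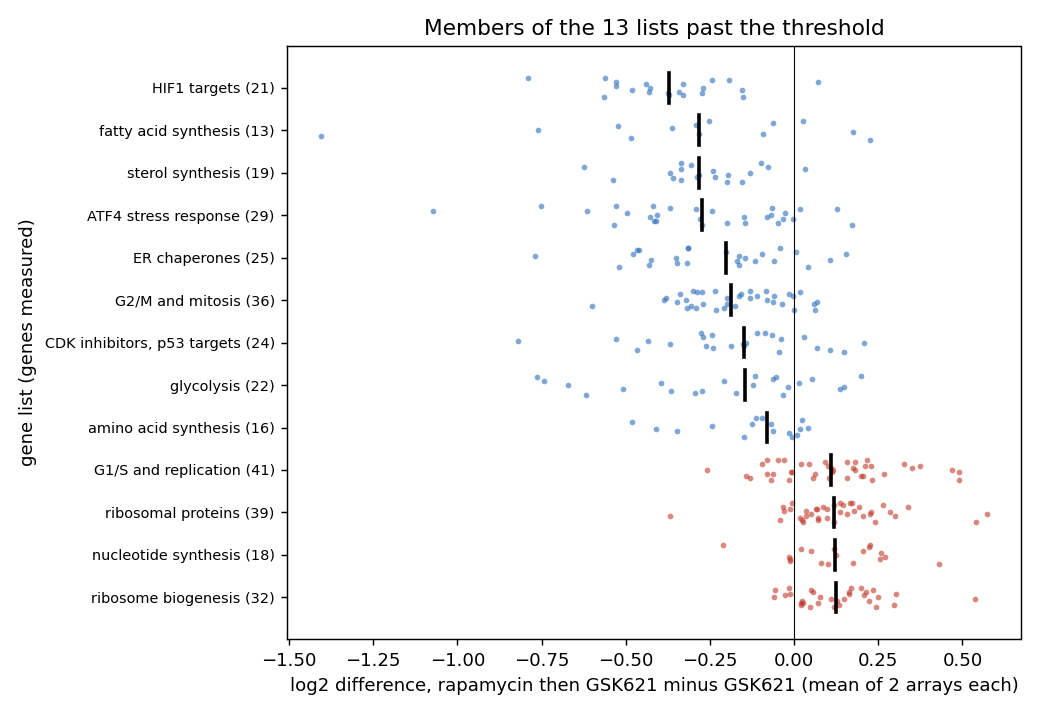
Log2 difference (rapamycin then GSK621 minus GSK621, means of 2 arrays each) of every measured member of the 13 lists past the threshold, with a point per gene, a black bar for the list median and the number of genes in brackets, blue for lists lower and red for lists higher after rapamycin. Medians run from −0.37 for HIF1 targets to 0.12 for ribosome biogenesis, and every list has members on both sides of 0.

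The other 23 lists did not pass. Closest were the pentose phosphate pathway (adjusted p = 0.0768), in which PGLS (0.43 ± 0.10) rose when adjusted over the list alone, and immediate early genes (0.121), in which IER3 (0.72 ± 0.11) did. With limma over all genes, the adjusted p was 0.447 for PGLS and 0.413 for IER3. Cytosolic heat shock genes and proteasome subunits both had an adjusted p of 0.125, genes of MLL-rearranged leukaemia 0.130, and cytosolic tRNA synthetases 0.230. Without replicate 1 of rapamycin then GSK621, immediate early genes (adjusted p = 0.0182, range over all settings 0.0182 to 0.751) and heat shock genes (0.00535, range 0.00535 to 0.769) passed. With a variance trend in camera 5 of these lists passed, namely pentose phosphate genes (adjusted p = 0.0200, range 0.0200 to 0.519), proteasome subunits (0.0308, range to 0.631), leukaemia genes (0.0308, range to 0.547), tRNA synthetases (0.0403, range to 0.844) and immediate early genes (0.0433). Of the leukaemia genes, RUNX1 had 0.38 ± 0.10, FLT3 0.34 ± 0.09 and LMO2 0.30 ± 0.09. Amino acid transporters (adjusted p = 0.478), lysosome and autophagy genes (0.595), MYC and its targets (0.738), FOXO targets with PI3K feedback genes (0.743) and mitochondrial ribosomal proteins (0.743) did not pass as lists. Within them WIPI1 and GPNMB (−0.81 ± 0.13) fell, CCNG2 (−0.75 ± 0.12) fell and TXNIP (0.72 ± 0.15) rose when adjusted over their list alone. Respiratory chain subunits, fatty acid oxidation genes and the eIF2 pathway each had an adjusted p of 0.934, the BCL2 family 0.922, NRF2 targets 0.898 and the subunits and regulators of AMPK and mTOR 0.963. ME1 and NQO1 (−0.52 ± 0.09) fell when adjusted over the NRF2 list alone.

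Markers of blood cell identity did not pass as lists, with adjusted p values of 0.888 for monocyte, 0.963 for granulocyte, 0.866 for erythroid and megakaryocyte and 0.534 for lymphoid genes. Adjusted over the monocyte list alone, TLR2 rose and S100A8 (−0.63 ± 0.10) and ANXA1 (−0.78 ± 0.14) fell. Adjusted over the granulocyte list alone, the azurophil granule protease CTSG (−0.74 ± 0.11) fell, and PRTN3 (0.43 ± 0.10) and CSF3R (0.43 ± 0.10) rose. With limma over all genes, the adjusted p of these monocyte and granulocyte genes ran from 0.228 for TLR2 to 0.489 for CSF3R. Cytokine and NF-κB target genes had an adjusted p of 0.806. Interferon-stimulated genes had an adjusted p of 0.374 between the treatments, with a range over all settings of 9.55e-06 to 0.978. They passed as lower without GSK621 replicate 1 (adjusted p = 2.72e-04) and without replicate 2 of rapamycin then GSK621 (9.55e-06), and as higher without replicate 1 of rapamycin then GSK621 (0.0242). Between replicate numbers, 29 of 30 interferon-stimulated genes were higher in replicate 2 in both groups. In 8 of the 36 lists, none of them past the threshold, the median, the mean and the test differed in sign.

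Camera with a preset correlation compares a list with the other genes and takes members as nearly independent, and it also called the interferon list between replicate numbers (adjusted p = 1.18e-20), a split that does not follow the treatment. In each of the 13 lists the estimated correlation gave the highest adjusted p of the 16 settings. In simulated data of this size it recovered 0 of 12 shifted lists where the preset correlation recovered 12. The simulated genes were independent, so this comparison favours the preset correlation and does not test it on members that move together. Over the 13 lists the estimated correlation ran from −0.020 for ATF4 genes to 0.484 for HIF1 targets, with 0.855 for interferon-stimulated genes. For ATF4 genes and chaperones (−0.0086) it lay below the preset 0.01, so a high correlation was not what cost these calls. The unadjusted p of camera for ATF4 genes was 9.14e-11 at the preset correlation and 0.0181 with the estimated one. Camera with an estimated correlation rests on the 2 residual degrees of freedom of the fit. For these 2 lists a lost call is therefore no evidence that members move together.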

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

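The level-dependent trend, protein-coding genes and genes in 1 list were settings chosen after seeing the data, and all others were planned. The count of genes was 0 with limma as reported and in each fit that left out an array, with 2064 at unadjusted p under 0.05. It was 3 (2 higher, 1 lower) with genes above the median level, where fewer genes were tested. With a variance trend and robust estimation it was 74 (20 higher, 54 lower), and the cause was not tested. In that setting the split by replicate number and the remaining split each gave 0, with the treatment difference in their residual. Without moderation the count between the treatments was 1 (1 lower). That gene, ATF2, had a log2 difference of −0.19 and passed on an SE of 1.74e-04, against a median SE of 0.11 with moderation. All other settings gave 0. The number of lists was 0 with an estimated correlation and 1 with fry, 18 with a variance trend and 12 to 15 when an array was left out, and 13 in the remaining settings. With the replicate number as a block there were 0 genes and 13 lists, and no other call changed. Deviations of same-numbered arrays correlated over genes at r = 0.0923, at 0.135 above the median level and at 0.0814 after quantile normalization, and 2 pairs without a stated shared day do not pair the arrays. The log2 difference of ATF4 turned to 0.0186 with quantile normalization and 0.00203 with centring, and ran from −0.0847 to 0.0800 when an array was left out, above 0 without GSK621 replicate 2 and without replicate 1 of rapamycin then GSK621. That of CHAC1 ran from −0.15 to 0.0199, above 0 without GSK621 replicate 2. That of IFIT1 ran from −0.59 to 0.0634, above 0 without replicate 1 of rapamycin then GSK621. Without that array the interferon list passed in the other direction (adjusted p = 0.0242), with 9.55e-06 to 0.120 over the arrays left out and up to 0.978 over all settings. When an array is left out, the lone array is assumed to vary like the other group. No signal over background was used, so what limits dim genes is open.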

Other observations

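The tests in this part were chosen after the list results were seen, except the fit of every probe set, which was fixed before the data were examined, and the matched-list test of transcripts with a terminal oligopyrimidine tract, a list written before its values were looked at.

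Metallothioneins, small metal-binding proteins, were not among the fixed lists and were looked at because MT1G stood among the lowest genes. All 11 measured metallothionein genes and pseudogenes had a lower mean after rapamycin and GSK621 than after GSK621 alone, as deposited and after quantile normalization, centring or trend removal, with overlapping arrays for the pseudogenes MT1L, MT1JP and MT1DP. Their median log2 difference was −0.49, and 7 of them had an unadjusted p under 0.05. MT1M had −2.33 ± 0.29 (SE, n = 2 per group), MT1E −0.77 ± 0.15, MT1F −0.71 ± 0.11, MT2A −0.65 ± 0.12 and MT1X −0.49 ± 0.10. The GSK621 arrays of MT1M lay apart, at 7.72 and 6.81. MT1B, MT1H, MT1L, MT1JP and MT1DP were dim, between percentiles 9.2 and 38.9 of mean level, so their direction is uncertain. These genes are near-identical copies, so the signal of each is uncertain and they do not count as separate genes, and the family was chosen because it holds MT1G. Over all genes 0 of the 11 passed with limma as reported, and 5 passed with a variance trend and robust estimation. The unnamed probe sets, tested together with the named ones, gave 0 past the threshold and 118 at an unadjusted p under 0.05.

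Joint movement of the fixed lists was set against 3 explanations. At the preset correlation the treatment split gave 13 lists and the highest of the other splits gave 1, so 1 of 3 splits gave as many, and 3 splits are too few for a share under 0.05. A level-dependent difference between arrays was not the whole cause, since the fitted trend was small (a shift of 0.029 at the 99th percentile of genes) and took away at most 19.4% of the median of any of the 13 lists. Genes shared between lists were not the whole cause either, since 13 of 13 lists kept their call at the preset correlation with shared genes left out, though 0 lists passed with an estimated correlation (smallest adjusted p = 0.367 with an estimated correlation) and 1 with fry. What stays open is chance, correlation between members of a list, rapamycin before GSK621 and any unrecorded difference between the cultures of the groups. With 2 arrays per group these are not separated.

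The rise of ribosomal protein transcripts may be a real difference in mRNA level, as a hypothesis from the same data. As a list they passed camera at the preset correlation only. The call was lost with an estimated correlation (adjusted p = 0.519) and with fry (adjusted p = 0.147). The list median lay at percentile 99.99 of random lists matched on level (range −0.04 to 0.07), which argues against a level-dependent trend as the whole cause. The fitted trend still took away 19.4% of this median, the most of the 13 lists, and left 0.0946. After quantile normalization the median was 0.0895. The brighter 19 members had a median of 0.14 against 0.09 for the other 20, which argues against a signal of dim members alone. Whether these probe sets also read related sequences was not tested. RPL19, named above, had a mean level of only 6.74 (percentile 67.6). Outside the ribosomal proteins, 15 measured transcripts with a terminal oligopyrimidine tract, whose translation depends on mTORC1, had a median of 0.0907 with 11 higher, at percentile 96.7 and inside the matched range of −0.08 to 0.10. Beside the fixed lists they passed camera at the preset correlation (adjusted p = 0.0444, adjusted p = 0.612 with an estimated correlation), so a rise of such transcripts as a class cannot be told apart from a change of ribosomal protein genes alone.

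Interferon-stimulated genes differed between replicate numbers, and a condition shared by cultures of the same number is a candidate explanation. In both groups 29 of 30 genes were higher in replicate 2, against 25% by chance for independent genes, but these genes move together, so the 2 groups give only 2 observations of direction and chance stays open. The median over both groups of replicate 2 minus replicate 1 was 0.29, outside the −0.04 to 0.03 of lists matched on level, which argues against a level-dependent trend. The group medians were 0.25 with GSK621 and 0.34 with rapamycin then GSK621, and IFI27 had the highest values, 1.43 and 1.30. The labels name no shared day or medium, and no biological explanation was tested.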
